A study of Glycine max with 8 samples.

How the data were processed

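Chromatin immunoprecipitation followed by sequencing (ChIP-seq) maps where a protein sits on DNA: crosslinked chromatin is sheared, fragments bound by the protein are collected with an antibody, and the collected DNA is sequenced. Here the antibody was raised against a peptide of the protein encoded by GLYMA.08G357600, and the tissue was soybean (Glycine max) embryos dissected at the mid-maturation stage, per the labels' protocols. Input libraries, made from chromatin set aside before the antibody step, served as controls. The labels gave 8 libraries: 4 ChIP and 4 input, each group made of 2 biological replicates sequenced on 2 lanes each. Lanes of a biological replicate were not treated as replicates.

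The values came from 2 deposited peak lists in the narrowPeak layout, 1 per ChIP biological replicate, in which the reads of both lanes appear to have been joined. No value of an input library was used on its own; input entered through the background against which the peak caller set each peak. Reads were aligned with Bowtie 0.12.7 and peaks called with MACS2, per the submitters' processing notes; the MACS2 version, the settings and the genome build are not given in the sources used here. Coordinates are those of the deposited lists, on sequences named as 20 chromosomes and numbered scaffolds, and are written counting from 1.

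Each deposited peak has a start, an end, a summit and 4 values from the peak caller. The fold enrichment is a ratio that the authors' peak caller computed at the summit, the number of overlapping fragments plus a pseudocount of 1 over the local background plus 1. The deposited −log10 p and −log10 q values come from a Poisson test of the summit against that background. The deposited score equalled the whole part of 10 times −log10 q in all but 3 replicate 1 peaks and in every replicate 2 peak. These values are the authors' own for each peak, and were used to describe, rank or filter peaks within their list.

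The summit pileup (overlapping fragments) and the local background were recovered by solving the fold and the Poisson p of each peak together. Pileups came out whole, within 0.01, for 100.0% of the 21196 replicate 1 peaks and 100.0% of the 18385 replicate 2 peaks. The lowest background of a list was taken as its genome-wide level, 3.91 fragments in replicate 1 and 2.74 in replicate 2, and about 27.7% and 27.8% of peaks sat on it. Most other backgrounds were whole multiples of the share of 1 input read in windows of 1 or 10 kb or of the fragment length (99.9% of them in replicate 1 and 99.6% in replicate 2, within 0.0003). The narrowest peaks, 223 bp and 221 bp, were taken as the fragment length of the caller. The input scale found this way corresponds to 1.70 times as many input reads as ChIP reads in replicate 1 and 2.44 times in replicate 2. Total read numbers per library are not used here, so only these relative depths are given; from the genome-wide backgrounds, each divided by its fragment length, the ChIP depth of replicate 1 was 1.41 times that of replicate 2.

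A reproducible (shared) region joined the full extent of peaks of both lists that overlapped by at least 1 bp. Where a region held more than 1 peak of a list, the peak with the highest fold gave its values, and the region summit was midway between the summits of the replicates. Overlap was compared with 1000 random placements of replicate 2 peaks on their own chromosomes, widths kept, by a one-sided permutation test. Percentages of peaks carry Wilson 95% intervals, which cover counting error only. The Spearman correlation of fold enrichment was taken across regions, which are not independent replicates, and so has no p. Regions were ranked by the mean of their percentile ranks in the 2 lists, and the 10 with the highest mean rank were named, a rule set before the data were examined. That rule also named the targeted gene, the gene nearest to each region and genes of chosen lists, which could not be applied without gene positions of the build.

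Results on chromosome position, spacing, pileup and background were chosen after the lists had been seen. Chromosome length was taken as the highest peak end in either list, and the outer parts as 20% of that length at each end. The share of regions there was compared with 1000 random placements along each chromosome. Spacing was compared with shifts of every summit by a random distance of up to 50 kb, which keeps density only over longer distances. Runs of regions were chains of summits each within 5 kb of the next. Pileups of the 2 replicates were compared by a two-sided exact binomial test per region with summits at most 100 bp apart. The expected ratio was the median over regions, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. A high background was more than 5 times the genome-wide level of the list.

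The steps were tested on simulated data with known answers. Pileups were recovered for 2000 of 2000 simulated peaks, which were made with the same formulas. Of peaks made as shared, 11031 of 11031 were found, as were 149 of 7354 placed at random. The shared ones had been moved by less than any peak's width, so both full scores check the code only. Of 200 regions changed by 2-fold the pileup test called 77, with 2 of 14800 unchanged regions. Of 200 changed by 3-fold it called 154, with 7 of 14800 unchanged. Pileups simulated for that test were higher at the median than those of the shared regions. For uniform summits the neighbour ratio was 1.06.

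Alternatives set before the data were examined were a reciprocal overlap of 50%, summits at most 100 bp apart, a −log10 q of at least 10, the 5000 peaks of each list with the highest −log10 q, peaks above the median fold, and counting single replicate 1 peaks. Others, added later, left out a replicate or changed distances, shifts, scaling or the background limit. Promoter location, promoter-bound genes, DNA motifs at summits, their co-occurrence, gene lists and motif content by strength had been planned but were not analysed here, since they need the genome sequence and gene positions of the build of the lists. The table of gene names at hand (assembly Glycine_max_v4.0) did not link the targeted identifier to a symbol, and none of its coordinates were used. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.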

Results

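Binding of the protein encoded by GLYMA.08G357600 was mapped by ChIP-seq in mid-maturation soybean embryos, the stage at which seeds store reserves. The design asked where in the genome the protein sits, with 2 biological replicates of ChIP and of input chromatin. Each ChIP replicate had a peak list of its own, called against input. Replicate 1 gave 21196 peaks, of which 21078 lay on the 20 chromosomes and 118 on 26 scaffolds. Replicate 2 gave 18385 peaks, 18292 on the chromosomes and 93 on 20 scaffolds. Peaks were narrow in both lists, with median widths of 372 bp and 363 bp, and covered 8.89 Mb and 7.42 Mb.

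Enrichment over the local background ranged widely within each list. In replicate 1 the median fold enrichment was 5.85, the quartiles 4.46 and 9.01, and the highest value 76.2. In replicate 2 the median was 6.67, the quartiles 5.07 and 10.4, and the highest value 87.1. A fold of at least 20 was reached by 1301 peaks of replicate 1 and 1536 of replicate 2. The median summit held 32 overlapping fragments in replicate 1 (range 14 to 410) and 28 in replicate 2 (range 12 to 402). The genome-wide background was 3.91 and 2.74 fragments, and after dividing each by the fragment length (223 and 221 bp) the ChIP depth of replicate 1 was an estimated 1.41 times that of replicate 2. The lowest −log10 q was 2.30 in replicate 1 and 2.00 in replicate 2. Whether the lists were called with different limits is not known, since the settings are not given.

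The first comparison asked whether both biological replicates marked the same places. They shared 15872 regions, 15792 on the chromosomes and 80 on scaffolds, with a median width of 453 bp and a total of 7.92 Mb. Of the replicate 1 peaks, 75.2% (15945, Wilson 95% interval 74.6% to 75.8%) overlapped a replicate 2 peak. Of the replicate 2 peaks, 87.0% (15996, interval 86.5% to 87.5%) overlapped a replicate 1 peak. Within shared regions the summits lay a median of 29 bp apart, and 92.7% of regions had summits at most 100 bp apart. Random placement gave mean overlaps of 1.65% and 1.90% and never above 1.90% and 2.18% (one-sided permutation p = 0.001 for each list, the smallest that 1000 placements can give). The labels call the replicates biological, but whether they came from separate chromatin preparations could not be checked from the lists; the overlap measures only the likeness of these lists. Moving peaks by at most 50 kb, which keeps them in the same neighbourhood, gave 3.87% and 4.52%.

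The strongest regions were strong in both replicates. Across shared regions the fold enrichment of the lists had a Spearman rho of 0.811 and the summit pileup a rho of 0.881; both run across regions, which are not independent replicates. A fold of at least 10 was found in both lists at 3870 regions and of at least 20 at 1133.

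**Figure D1:**
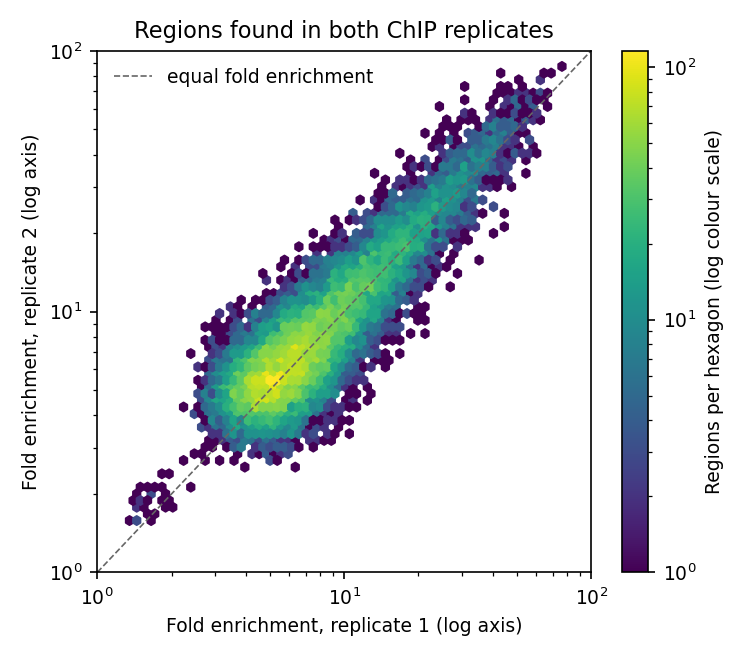
Fold enrichment of the 15872 shared regions in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), coloured by the number of regions per hexagon, with a dashed line at equal values. The regions form a band along the line (rho 0.811), and a small separate group lies near the lower left corner, at folds around 1.62 in replicate 1 and 1.93 in replicate 2.

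The top region was the same peak in both lists, on chromosome 3 from 37825187 to 37826325, with fold enrichments of 76.2 in replicate 1 and 87.1 in replicate 2 and summit pileups of 395 and 372 fragments. It was followed by a region on chromosome 11 from 34413697 to 34415199 (folds of 70.9 and 82.8). Chromosome 10 held the next, from 39002970 to 39004185 (66.3 and 80.8), and a further one from 40797448 to 40798472 (61.9 and 75.9). Between these in rank stood a region on chromosome 9 from 46609076 to 46609919 (62.2 and 78.0). Chromosome 20 held regions from 35315097 to 35316250 (67.9 and 69.8) and from 45538082 to 45538888 (62.1 and 69.8). Chromosome 13 also held a pair, from 23668336 to 23669237 (61.4 and 69.2) and from 31638689 to 31639605 (62.8 and 65.0). The set of 10 was completed by a region on chromosome 5 from 38326156 to 38327172 (60.4 and 67.4). All 10 were between 807 and 1503 bp wide. Genes at these places are not reported, because the build of the coordinates is not given in the sources used here.

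The 100 regions with the highest ranks were spread over 19 chromosomes and 2 scaffolds. Chromosome 11 held 9 of them, chromosomes 10 and 13 held 8 each, chromosome 9 held 7, and chromosome 1 held none. Strong regions tended to be wide, with a rho of 0.651 between width and rank across regions, and 383 regions exceeded 1000 bp. The widest lay on chromosome 14 from 1170614 to 1173759, 3146 bp long with folds of 9.61 and 9.62. Next in width were regions on chromosome 17 from 4090183 to 4092753 (22.1 and 29.5) and on chromosome 1 from 3715105 to 3717531 (14.9 and 16.3). Width depends on the caller, which merges summits that lie close together. A taller pileup can also stay above the caller's limit over a longer stretch, so this rho is no separate evidence about binding.

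Peaks found in 1 replicate were mostly weaker than shared ones, and all had a fold under 10. In replicate 1, 41.4% of the quintile with the lowest fold enrichment overlapped replicate 2, then 55.6%, 81.5% and 97.7%, and 100.0% of the quintile with the highest fold. In replicate 2 the corresponding shares were 65.1%, 77.2%, 93.3%, 99.5% and 100.0%. None of the 4475 replicate 1 peaks or 4887 replicate 2 peaks with a fold of at least 10 lacked a partner. The 5251 unmatched replicate 1 peaks had a median fold of 4.28 and a median pileup of 23 fragments, against 6.93 and 39 for matched peaks. The 2389 unmatched replicate 2 peaks had 4.72 and 19, against 7.24 and 30.

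**Figure D2:**
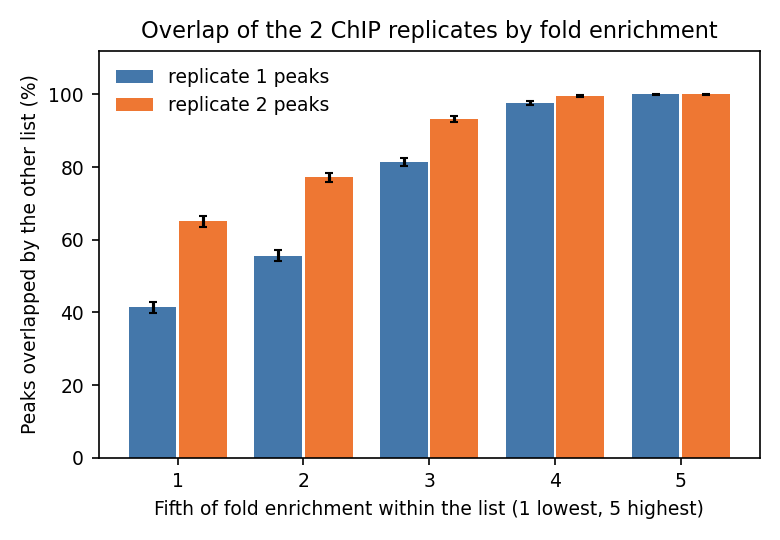
Percentage of peaks overlapped by the other list (vertical) in quintiles of fold enrichment within each list (horizontal, lowest to highest), for replicate 1 (blue) and replicate 2 (orange), with Wilson 95% intervals as error bars. Overlap climbs from 41.4% and 65.1% in the lowest quintile to 100.0% in the highest quintile of both lists.

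The strongest unmatched replicate 1 peaks lay on chromosome 8 from 2698709 to 2699062 (fold 9.05), on chromosome 11 from 26490233 to 26490730 (8.77) and on chromosome 17 from 37882295 to 37882664 (8.77). In replicate 2 they lay on chromosome 20 from 37172800 to 37173120 (9.61), chromosome 15 from 4222153 to 4222577 (9.44) and chromosome 13 from 40401067 to 40401445 (9.18). These were picked after their values were seen. A missing peak in a list of calls is no measurement of 0 at that place.

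No region was detected whose pileup departed from the median ratio of the replicates. At 14708 regions with summits at most 100 bp apart, the replicate 1 pileup was a median of 1.25 times the replicate 2 pileup. Given that ratio, 0 regions differed by an exact binomial test after Benjamini-Hochberg adjustment, and the lowest adjusted p was 0.588 (exact binomial test). Without adjustment 393 regions (2.67%) had an exact binomial p under 0.05. That is a smaller share than the threshold allows by counting error, so the test was probably conservative here. Among the quintile of regions with the highest total pileup, the log2 ratio had an SD of 0.196, against 0.205 from counting error alone. The spread between regions there was thus no larger than that counting error. Each pileup was read at the summit of its own list, for which this error may be an inexact measure. A cap on reads at the same position, discussed below, could narrow that spread, so extra variation between the replicates is not excluded. The ratio was not the same throughout, since the 100 regions with the highest pileup had a median log2 ratio of 0.17, against 0.34 in the quintile below. The test sets 1 list against 1 list and covers counting error only, with overlapping fragments taken as independent. It called 77 of 200 simulated 2-fold changes, at simulated pileups higher at the median than those of the shared regions. Changes of that size could therefore have been missed, and the share called at the observed pileups may be lower. Below the highest quintile the SD was 0.312, 0.353, 0.333 and 0.280 from lowest to highest, against 0.441, 0.390, 0.346 and 0.289 from counting error. Regions had to be called in both lists, which may narrow the spread of weak ones, but this was not tested. No other pair of ChIP replicates was at hand for comparison. Scaling by the background depth ratio of 1.41 instead called 4 regions, and taking summits at any distance called 1.

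Regions were concentrated toward the ends of the chromosomes. The outer 20% at each end held 10778 of the 15792 chromosomal regions, or 68.2%, where random placement gave a mean of 40% and at most 41.4% (one-sided permutation p = 0.001, the smallest possible). The share was above 40% on 19 of the 20 chromosomes, with a mean of 69.5% ± 10.9 (SD, n = 20 chromosomes). It was highest on chromosome 4, at 86.9%, then on chromosome 14, at 78.4%, and chromosome 1, at 77.4%. Chromosome 13 was the exception, at 33.4%. The outermost 10% at both ends together held 6181 regions and the middle 20% held 940, a ratio of 6.58. Fold enrichment was alike across this layout, with median folds of 6.93 and 7.21 in the outermost parts and of 7.03 and 7.27 in the middle. The random placements were uniform along each chromosome and took no account of where genes lie. Whether the layout of regions goes beyond that of genes was not tested.

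**Figure D3:**
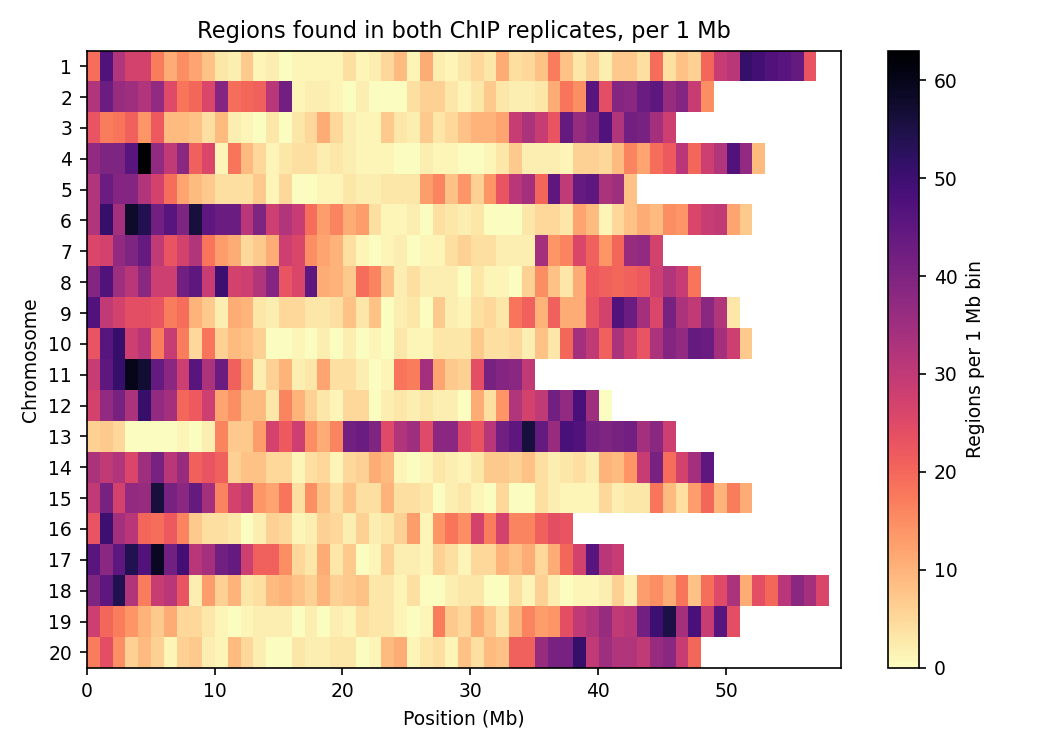
Number of shared regions per 1 Mb (colour) along the 20 chromosomes (rows), by position in Mb (horizontal). Dark bins gather toward the ends of most chromosomes; chromosome 13 is instead sparse near its start and dense over the rest, and the fullest bin, with 63 regions, lies on chromosome 4.

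Chromosome 13 also had the most regions, 1163, and the highest density, 25.4 per Mb, against a mean of 16.9 ± 3.59 per Mb (SD, n = 20 chromosomes). Its first 10% held 18 regions and its second 10% held 1, while the last 3 segments of 10% held 208, 194 and 176. Chromosome 11 came next in density, with 23.7 per Mb, then chromosome 17 with 21.1. Chromosomes 18 and 1 were the sparsest, with 12.8 and 13 per Mb. The densest 1 Mb bins lay on chromosome 4 from 4000001 (63 regions), chromosome 11 from 3000001 (60) and chromosome 17 from 5000001 (59), where the median over all bins was 11. The longest stretches without a peak in either list were on chromosome 6 from 30790182 to 34423834 (3.63 Mb), chromosome 20 from 13737548 to 16566742 (2.83 Mb) and chromosome 18 from 30509694 to 33171140 (2.66 Mb). Chromosome lengths were taken from the last peak, and which parts of the genome could be aligned is not known here, so the random placements allow positions where no peak could be called.

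Shared regions also lay close to one another more often than after random shifts of up to 50 kb. Within 2 kb of each other lay 1454 neighbouring pairs, against a mean of 1009 and at most 1091 after shifts of up to 50 kb, a ratio of 1.44 (one-sided permutation p = 0.001, the smallest possible). By distance, pairs 0.5 to 1 kb apart numbered 474 against 254 after shifts, pairs 1 to 1.5 kb apart 506 against 247, and pairs 1.5 to 2 kb apart 453 against 244. The excess shrank to 1.4 times at 2 to 3 kb and 1.16 times at 3 to 5 kb, and at 5 to 10 kb the ratio was 0.935. Under 0.5 kb only 21 pairs were found against 262, which follows from peaks being at least 221 bp wide and merged where they touch. For that reason the ratio over all pairs within 1 kb was 0.955. The ratio within 2 kb depended on the shift, at 1.34 for shifts of up to 20 kb and 1.55 for up to 200 kb. Simulated uniform summits, with no excess built in, gave 1.06.

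**Figure D4:**
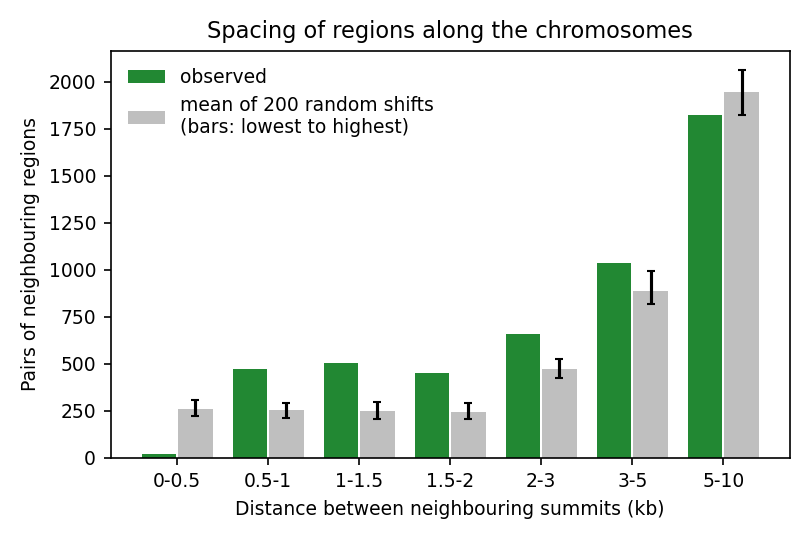
Pairs of neighbouring shared regions (vertical, count) by distance between their summits in kb (horizontal), as observed (green) and as the mean of 200 random shifts of up to 50 kb (grey, bars from the lowest to the highest shift). Observed pairs exceed every shift from 0.5 to 5 kb, with 506 pairs against 247 at 1 to 1.5 kb.

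Runs of at least 5 regions, each within 5 kb of the next, numbered 36, against a mean of 13.5 and at most 23 in 200 shifts (one-sided permutation p = 0.005, the smallest possible). The longest held 7 regions and lay on chromosome 9 from 4122885 to 4132810 (replicate 1 folds of 4.69 to 17.9), chromosome 13 from 34669749 to 34681807 (4.93 to 15.6) and chromosome 5 from 40535058 to 40545171 (4.95 to 9.58). Runs of 6 lay on chromosome 18 from 2729497 to 2737329, with folds from 7.54 to 56.7, and on chromosome 1 from 55139412 to 55146966, with folds from 4.03 to 22.2. Shifts gave runs of up to 11 regions, longer than any observed, although shifted summits can fall closer together than merged peaks allow. No likeness in strength between neighbours was detected: the rank correlation of neighbouring regions was 0.0457 within 1 kb, and none of 5 distance classes passed adjustment (lowest adjusted permutation p = 0.2645).

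Scaffolds outside the chromosomes held 80 shared regions. Scaffold 21 held 31 of them, with folds of up to 59.9 in replicate 1 and 56.9 in replicate 2, and scaffold 28 held 11, with folds of up to 57.1 and 62.2. Scaffold 27 held 10, with folds of up to 25.9 and 28.8. Each of these scaffolds therefore had regions in the range of strong chromosomal ones.

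A small group of regions had a high input background. More than 5 times the genome-wide background was found at 42 replicate 1 peaks and 85 replicate 2 peaks, and at 33 regions in both. The background is the denominator of the fold, and these 33 had median folds of 1.62 and 1.93, although their median pileups were 247 and 204 fragments. Chromosome 12 held 5 of them from 39184619 to 39194453, over 9.84 kb, with backgrounds of 139 to 206 fragments in replicate 1 and 98.5 to 167 in replicate 2 and folds of 1.46 to 1.93. The highest background of a shared region, 222 fragments in replicate 1, was on chromosome 13 from 16858799 to 16859413 (folds of 1.47 and 1.59).

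**Figure D5:**
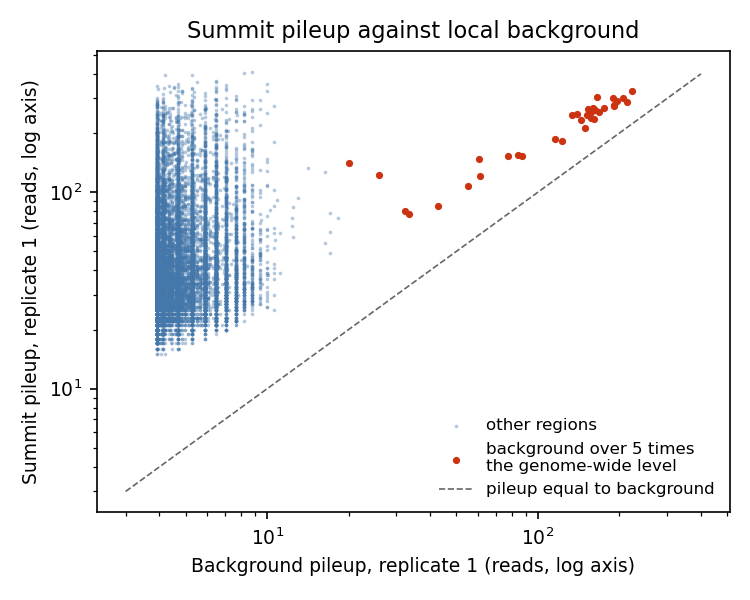
Summit pileup (vertical, fragments, log axis) against local background (horizontal, fragments, log axis) for shared regions in replicate 1, with regions above 5 times the genome-wide background in red and equality as a dashed line. Most regions stand at low backgrounds, with a median of 4.59 fragments over matched replicate 1 peaks. Most red points run close above the line, up to a background of 222. Among regions high in both lists the highest replicate 1 fold was 4.58.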

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

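Tests on chromosome position, spacing, pileup and background, and their alternatives, were chosen only after the lists had been seen, as were placements within 50 kb and the count without high-background regions; the other overlap alternatives were set before. Of 45 alternatives run, 38 kept their direction and their side of the threshold, or, for values with no test, stayed within the error of the value or within 1.5 times the count. Among these, shared regions numbered 10708 with a −log10 q of at least 10, and the outermost 10% at each end held 39.1% of regions, against 20% by random placement. The number of shared regions fell to 4351 with the 5000 peaks of highest −log10 q per list and to 7946 with peaks above the median fold, which follows from the smaller lists. The rho of fold enrichment was 0.819 with summits at most 100 bp apart and 0.804 for the top 5000 peaks; the cause was not tested. The neighbour ratio reversed to 0.955 within 1 kb, since merged peaks leave few pairs under 0.5 kb (21). The count of regions with different pileup was 4 under the background depth ratio (1036 at an unadjusted binomial p under 0.05). That setting moved the expected ratio from the observed median of 1.25 to 1.41, so regions at the usual ratio stood further from it. What set the 4 regions apart was not tested. With summits at any distance 1 region was called (417 unadjusted). Its summits lay 178 bp apart, and so it was outside the main set. Leaving out a ChIP replicate gave outer shares of 68.0% to 68.6% and neighbour ratios of 1.5 to 1.52. Not run were 54 alternatives set before the data were examined, those for promoters, promoter-bound genes, motifs, motif co-occurrence, gene lists and motif content by strength. No paired analysis was possible because the only lists used were those of ChIP, and the input background is known only at called ChIP peaks, so ChIP and input could not be tested as groups. At simulated pileups, higher at the median than the observed ones, the pileup test called 77 of 200 simulated 2-fold changes.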

Other observations

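All tests in this part were chosen only after the results were seen. The 4 regions called under the background depth ratio lay on chromosome 2 from 11676176 to 11677242 and from 15727797 to 15728322, chromosome 10 from 42600950 to 42602086, and chromosome 20 from 43441197 to 43442262. The chromosome 2 region from 15727797 had 47 fragments in replicate 1 and 80 in replicate 2, with folds of 6.43 and 17.3. The other 3 had nearly equal pileups in both replicates: 230 and 250, 405 and 402, and 393 and 394. The region called with summits at any distance was on chromosome 12 from 39184619 to 39185755, within the group of high background, and its summits lay 178 bp apart.

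Peaks of replicate 1 without a partner in replicate 2 made up 58.6% of the quintile with the lowest fold enrichment, and 0 of 4239 in the quintile with the highest (Wilson 95% upper limit 0.0905%). The count of 0 argues against a near-complete loss of strong sites in replicate 2. A smaller difference would leave a called peak and is not excluded by it. Many of the unmatched peaks may be near the limit of calling, but not all were. The strongest unmatched replicate 1 peaks named above had a −log10 q of 26.2 to 30.0, against a list median of 14.4. Differences in weak binding between the replicates stay open, since a peak absent from a list has no value there.

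The pileup ratio of the replicates was smaller at the regions with the highest pileup. It did not fall steadily, since the quintile with the lowest total pileup had a median log2 ratio of 0.31, against 0.36 in the next. The median log2 ratio was 0.17 (bootstrap 95% interval 0.147 to 0.177) over the 100 regions with the highest pileup and 0.34 over the next lower quintile. One hypothesis is a cap on reads at the same position and strand, which would limit a summit to 446 fragments in replicate 1 and 442 in replicate 2; the highest seen were 410 and 402. Correcting for such a cap gave 0.28 (0.243 to 0.309) and 0.36 (0.347 to 0.369), a gap of 0.08 in place of 0.17. The correction assumes reads spread evenly around the summit, so whether the cap could account for the whole gap stays open, as does a true difference between replicates.

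The regions with high background combined tall pileups with low enrichment. Their median replicate 1 fold was 1.62, at a median background of 152 fragments. If the cap of 446 held, which was not shown, a summit at that median background could reach a fold of 2.93 at most. Single regions of the group went higher, with folds of up to 4.58 in replicate 1 and 6.15 in replicate 2. Their median pileup less background was 87.3 fragments, against 34.1 at the other regions. Such a cap could also limit the input reads behind the background, which was not corrected for. The excess in fragments is therefore no measure of binding. Whether binding there was as strong as elsewhere therefore stays open. Chance calls in 1 list are argued against for replicate 1, where 85.7% of such peaks (36 of 42) overlapped replicate 2; of the replicate 2 peaks 38.8% (33 of 85) overlapped replicate 1. Sequences present in more copies in the plants than in the build may explain high counts in both ChIP and input, which was not tested, since it needs the genome sequence.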
